A study of Mus musculus with 90 samples.

How the data were processed

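The series holds 90 samples of mouse embryonic stem cells, with V6.5 the line the labels name, and of embryoid bodies, among them ChIP-seq, RNA-seq and 4C-seq libraries from wild-type, Mll2-deficient and Mll2-mutant cells and from cells with hairpins against GFP, Mll2 or Menin. Peak lists of 5 ChIP-seq libraries were analysed. They came from the H3K4me3 ChIP of control hairpin cells (replicates 1 and 3, antibody 28), from Mll2 ChIP with serum 9172 and with serum 9175, and from Menin ChIP. The Mll2 libraries were of wild-type cells, and the title of the Menin library names no hairpin. Overlaps of Mll2 or Menin with H3K4me3 therefore compare different cell preparations. The RNA-seq, 4C-seq, mutant and knockdown samples were not analysed here, so no comparison between genotypes or hairpins was made. Each library was assigned to its group from its title or its antibody label.

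The authors called peaks with MACS 1.4.2, per the file headers, separately for each library against 1 input library, with a p cutoff of 1e-05 and with 1 tag kept per position. Per the file headers both Mll2 libraries had the same input, with 20878021 kept tags, while the inputs of H3K4me3 replicate 1, H3K4me3 replicate 3 and Menin were different ones with 27559315, 13831407 and 14562085 kept tags. The submitters' processing notes name CASAVA 1.8, Bowtie 0.12.9, TopHat2 2.0.13, MACS 1.4.2 and edgeR 3.0.8 for the series as a whole and the build mm9. The deposited tag count of a peak is a whole number of ChIP tags in the peak, not normalized. The deposited fold enrichment is a ratio of ChIP tags to a background that MACS estimated. The median serum 9172 fold at H3K4me3 regions was the same value, 16.41, on many autosomes. Such repeats point to a fixed background at many peaks, so the fold is not always a ratio to local input. The deposited score of a peak is minus 10 times the log10 of its MACS p, and it reached a ceiling in the strongest H3K4me3 peaks, so peaks were ranked by fold enrichment. The deposited false discovery rate is given in percent, and no listed peak exceeded 0.95%, a limit that no source used here states. Peak starts counted from 1, since width equalled end minus start plus 1 in each row. Fold enrichment and score are the authors' values of each peak and were used to describe, rank or filter peaks within a list. Fold enrichment was also related between the 2 sera and used to form strata of H3K4me3 regions. Tags per kb divided by fold served as a rough stand-in for the background, compared between chromosome X and autosomes within each library.

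Keeping 1 tag per position limits the tags that a narrow, strong peak can gather, which can compress the fold enrichment of the strongest H3K4me3 peaks. The share of tags removed as duplicates was 17% and 10% in the H3K4me3 libraries, 17% and 14% in the Mll2 libraries (serum 9172 first) and 4% in the Menin library. For the ChIP libraries the depth ran from 11550409 to 21936546 kept tags, so a peak missing from a list is a site not called at that depth and not a site without signal.

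Lists were compared by overlap of at least 1 bp. H3K4me3 regions were merged regions that held a peak of both libraries, and Mll2 regions were merged regions that held a peak of both sera. Shares have exact Clopper-Pearson 95% intervals. Overlaps were tested against 1000 circular shifts of the first list, each chromosome moved by 1 random distance, one-sided, with the smallest p being 0.001. The joint presence of Mll2 and Menin over H3K4me3 regions was tested with Fisher's exact test, two-sided, and within strata by the Mantel-Haenszel odds ratio. Median widths were compared with a two-sided permutation test of 100000 permutations. Fold enrichments of the sera were related on a log2 scale by Spearman's rho and Pearson's r across regions, with permutation p-values. Regions of a library are not replicates, and none of these tests measures the spread between cultures. Named regions were chosen by a rule set before the data were examined. Per comparison it took the 5 shared regions with the highest fold enrichment in the first list and, for regions without overlap, the 5 with the highest fold enrichment in their own list. The text gives a selection of these, made after their values were seen.

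Alternatives listed before the data were examined were an overlap of at least 50% of the shorter peak, a score of at least 100, a fold enrichment of at least 10, a false discovery rate of at most 1%, equally long lists, autosomes only, summits within 500 bp, each H3K4me3 library or Mll2 serum alone, peaks of either serum, strata of width, and tags per kb in place of fold enrichment. Shifts of 50 kb to 1 Mb and strata of H3K4me3 fold enrichment were added after the data were seen. The overlap test was tested on simulated lists made from the H3K4me3 replicate 3 list (19912 peaks) and the serum 9175 list (26388 peaks). With 60% of positions kept it found 60.8% and 60.7% and passed 0.05 in 5 of 5 runs for each list, and with 0% kept it found 2.6% and 2.3% and passed in 0 of 5. The lists with 0% kept were made by the same shifts that the test uses. They therefore could not show how often unrelated lists that cluster in the same parts of a chromosome would pass. The width test passed 0.05 in 20 of 20 runs with 100 bp added and in 1 of 20 with none, on 19912 peaks.

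The gene annotation at hand is of build GRCm38, while the peaks are in mm9. Coordinates were not converted, so regions are given by position, and whether they lie in a gene, exon, intron or promoter was not analysed here. For this reason 6 of the 15 planned results were not run. These were the distance of Mll2 and of H3K4me3 regions to transcription start sites, the relation of Mll2 to start sites over H3K4me3 regions, CpG density, gene groups with Mll2 at their start sites, and the loci of the 4C viewpoints. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.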

Results

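The series studied how the histone methyltransferase Mll2, a catalytic subunit of COMPASS-type complexes, contributes to trimethylation of lysine 4 of histone H3 (H3K4me3), a mark of active and poised promoters, in mouse embryonic stem cells of the line V6.5. Of its 90 samples, 5 chromatin immunoprecipitation (ChIP-seq) libraries with peak lists were analysed here. They were H3K4me3 replicates 1 and 3 from cells carrying a control hairpin against GFP, 1 Mll2 library from serum 9172, 1 Mll2 library from serum 9175, and 1 library for Menin, a protein that binds Mll1 and Mll2 and belongs to their complexes. The Mll2 libraries were of wild-type cells, so H3K4me3 was not measured in the same cell preparations. The lists held 25754 and 19912 H3K4me3 peaks, 25982 and 26388 Mll2 peaks, and 43544 Menin peaks. After removal of duplicate tags the libraries kept 21936546 tags for H3K4me3 replicate 1, 12277583 for replicate 3, 19584961 for serum 9172, 13739094 for serum 9175 and 11550409 for Menin. Peaks took up 50.9% and 46.8% of the kept tags of the H3K4me3 libraries, 9.7% and 12.4% of those of the Mll2 libraries, and 22.5% of those of the Menin library. Each Mll2 serum and Menin had 1 library, and nothing in the labels says whether the 2 H3K4me3 libraries came from separate cultures. The p-values of overlaps therefore compare peak lists with chance placement along the genome, those of the other tests concern association across regions of these libraries, and intervals on shares cover counting error only.

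To ask how well the H3K4me3 landscape repeated between libraries, peaks of replicates 1 and 3 were overlapped. Replicate 3 peaks lay almost entirely within the replicate 1 list, with 97.9% of them overlapped (95% interval 97.7 to 98.1%), and 417 peaks were found in replicate 3 alone. In the other direction 75.2% of replicate 1 peaks were overlapped (74.7 to 75.7%), which left 6389 peaks in replicate 1, the library with more tags. Those 6389 peaks were weak, with a median fold enrichment of 7.46 and a median width of 749 bp, against 39.0 and 1846 bp for the replicate 1 peaks that replicate 3 shared. Ranked by replicate 1 fold enrichment, the strongest shared region lay on chromosome 12 from 8646761 to 8648754 (mouse build mm9), with fold enrichments of 137 in replicate 1 and 96.9 in replicate 3. It was followed by regions on chromosome 16 from 32245564 to 32248492 (135 and 86.6) and on chromosome 10 from 107597814 to 107601426 (131 and 103), and all 3 also held Mll2 peaks of both sera and a Menin peak. Among peaks without a counterpart, the highest fold in replicate 1 was 36.9, on chromosome 9 from 120072893 to 120073843, and the highest in replicate 3 was 28.2, on chromosome 9 from 78669350 to 78669913. Shifted placements of the list gave a mean overlap of 2.63% of replicate 1 peaks and at most 3.76% in 1000 shifts (one-sided permutation p = 0.001, the smallest that 1000 shifts can give).

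Mll2 occupancy was compared between the 2 sera, which recognise the same protein. Serum 9175 found 80.7% of the serum 9172 peaks (80.2 to 81.1%), and serum 9172 found 77.4% of the serum 9175 peaks (76.9 to 77.9%), against 2.25% and 2.19% in shifted placements (one-sided permutation p = 0.001 for each). Peaks seen with both sera were the stronger ones, with median fold enrichments of 12.9 in serum 9172 and 15.2 in serum 9175, against 7.58 and 8.15 for peaks seen with a single serum. The strongest regions in serum 9172 lay on chromosome 7 from 128849771 to 128851551 (fold 151, and 79.9 in serum 9175), chromosome 14 from 27353090 to 27355033 (131 and 62.8) and chromosome 4 from 70070843 to 70072137 (122 and 44.8). All 3 also carried H3K4me3 in both libraries and Menin. A few strong peaks were specific to a serum. One on chromosome 2 from 31146876 to 31147440 reached a fold of 44.8 in serum 9172, and one on chromosome 8 from 95137266 to 95137901 reached 54.6 in serum 9175, and neither overlapped a peak of any other list. Over the 20082 regions that held a peak of both sera, called Mll2 regions below, log2 fold enrichments in the sera rose together, with Spearman's rho of 0.827 and Pearson's r of 0.821 across regions (permutation p = 1e-05 each, the smallest that 100000 permutations can give), regions not being independent replicates. Both Mll2 libraries were called against the same input, so part of their overlap may come from that input. This part was not separated here.

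**Figure D1:**
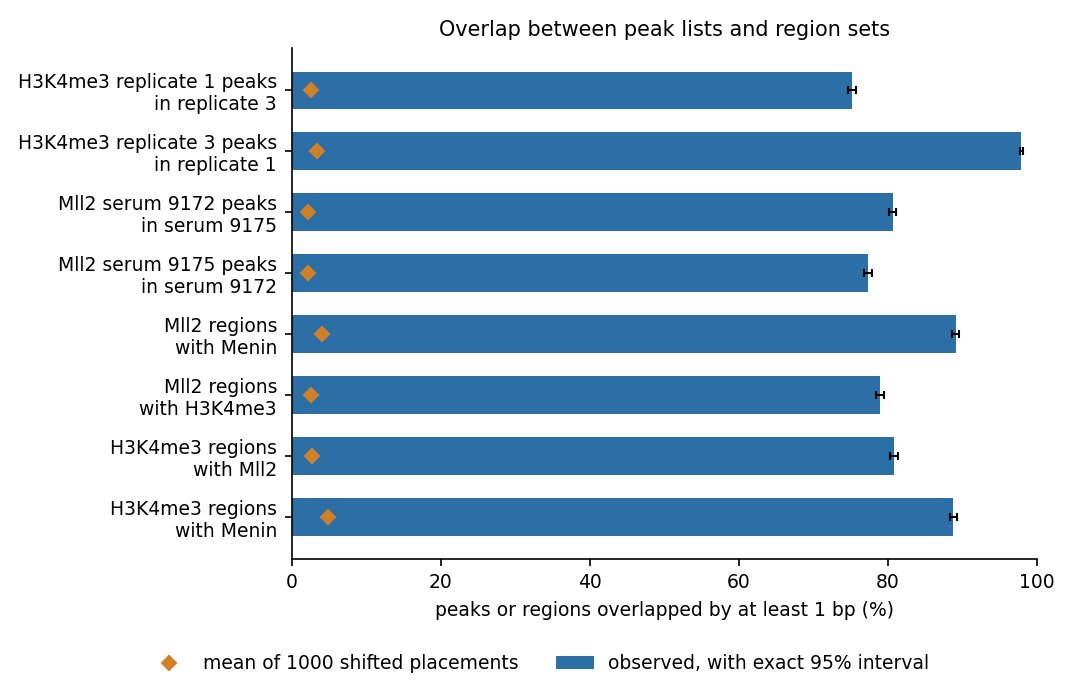
Horizontal bars give the share of peaks or regions, in percent, overlapped by at least 1 bp by the other list, with exact 95% binomial intervals as black lines, and diamonds give the mean over 1000 shifted placements. Observed shares ran from 75.2% for H3K4me3 replicate 1 peaks to 97.9% for replicate 3 peaks, far above the diamonds at each bar.

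Whether Mll2 sat where H3K4me3 was found was asked next. Of the 20082 Mll2 regions, 79.0% overlapped an H3K4me3 region present in both libraries (78.4 to 79.6%), and 85.1% overlapped an H3K4me3 peak of at least 1 library. Mll2 regions with H3K4me3 were more strongly occupied, with a median fold enrichment of 17.9 in serum 9175 and a median width of 1348 bp, against 9.10 and 814 bp for those without it. In the weakest decile of Mll2 regions by serum 9175 fold enrichment 40.8% carried H3K4me3, and in the strongest decile 99.8% did. By serum 9172 fold enrichment, the strongest Mll2 regions without an H3K4me3 region of both libraries lay on chromosome 7 from 51526470 to 51527322 (fold 70.9 in serum 9172 and 22.01 in serum 9175, with no H3K4me3 or Menin peak) and on chromosome 4 from 10786735 to 10787870 (56.9 and 17.4, with H3K4me3 in replicate 1 at a fold of 14.3). Another on chromosome 4, from 116861918 to 116863482, had folds of 51.5 and 20.4 and a Menin peak at 7.95. One on chromosome 9, from 65048472 to 65050202, had folds of 49.2 and 25.3 and an H3K4me3 peak in replicate 1 at 7.05. Shifted placements gave a mean overlap of 2.66% (one-sided permutation p = 0.001).

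Menin accompanied Mll2 at most of these sites. Of the Mll2 regions 89.1% overlapped a Menin peak (88.7 to 89.5%), rising to 96.8% of those with H3K4me3 and falling to 60.04% of those without it. Mll2 regions with Menin had a median fold of 16.7 in serum 9175, and the 2187 without Menin a median of 9.10. By serum 9172 fold enrichment, the strongest Mll2 region without Menin lay on chromosome 12 from 70461479 to 70462290, with folds of 85.8 in serum 9172 and 13.9 in serum 9175 and an H3K4me3 peak in replicate 1 at 63.1. That peak was part of an H3K4me3 region of both libraries, although no replicate 3 peak overlapped the Mll2 region itself. Conversely, the strongest Menin peaks outside the Mll2 regions lay on chromosome 2 from 165372683 to 165373370 (Menin fold 91.2) and chromosome 8 from 126938675 to 126939390 (87.6), and each overlapped a serum 9172 peak, at folds of 15.7 and 17.3, that serum 9175 did not list. A Menin peak on chromosome 4 from 139603665 to 139604449, at a fold of 39.7, overlapped no peak of the other 4 lists. Shifted placements of the Mll2 regions gave a mean of 4.10% (one-sided permutation p = 0.001).

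Seen from the mark, the 18894 H3K4me3 regions found in both libraries fell into 4 classes. Mll2 and Menin were both present at 78.7% of them (14877 regions), Menin without an Mll2 region at 10.0% (1897 regions), Mll2 without Menin at 2.08% (393 regions), and neither at 9.14% (1727 regions). In total 80.8% of H3K4me3 regions held an Mll2 region (80.3 to 81.4%) and 88.8% a Menin peak (88.3 to 89.2%). The share with a peak of at least 1 Mll2 serum was 89.6%. H3K4me3 itself was strongest where both proteins were present, with a median fold of 47.9 in replicate 1, against 20.7 with Mll2 alone, 12.8 with Menin alone and 14.1 with neither, and replicate 3 gave 45.4, 14.4, 10.3 and 11.3. Coverage by Mll2 rose from 42.0% of regions in the weakest decile of H3K4me3 fold enrichment to 99.5% in the strongest decile, and coverage by Menin from 72.8% to 99.3%. Among the strong H3K4me3 regions without an Mll2 region were 2 on chromosome X, from 101174063 to 101177452 (folds of 105 and 89.1 in the H3K4me3 libraries) and from 71541666 to 71543575 (96.8 and 88.4), both with Menin. The first of these overlapped a serum 9172 peak at a fold of 8.95, and Mll2 fold enrichment was generally lower on this chromosome, with a serum 9175 median of 12.2 against 18.8 on autosomes at regions listed in all 5 libraries. Others lay on chromosome 16 from 37653142 to 37655207 (86.9 and 73.0, with Menin and a serum 9172 peak at a fold of 7.69) and on chromosome 7 from 74792022 to 74793644 (81.5 and 38.6, with neither Mll2 nor Menin). Shifted placements gave means of 2.75% for Mll2 and 4.94% for Menin (one-sided permutation p = 0.001 each).

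**Figure D2:**
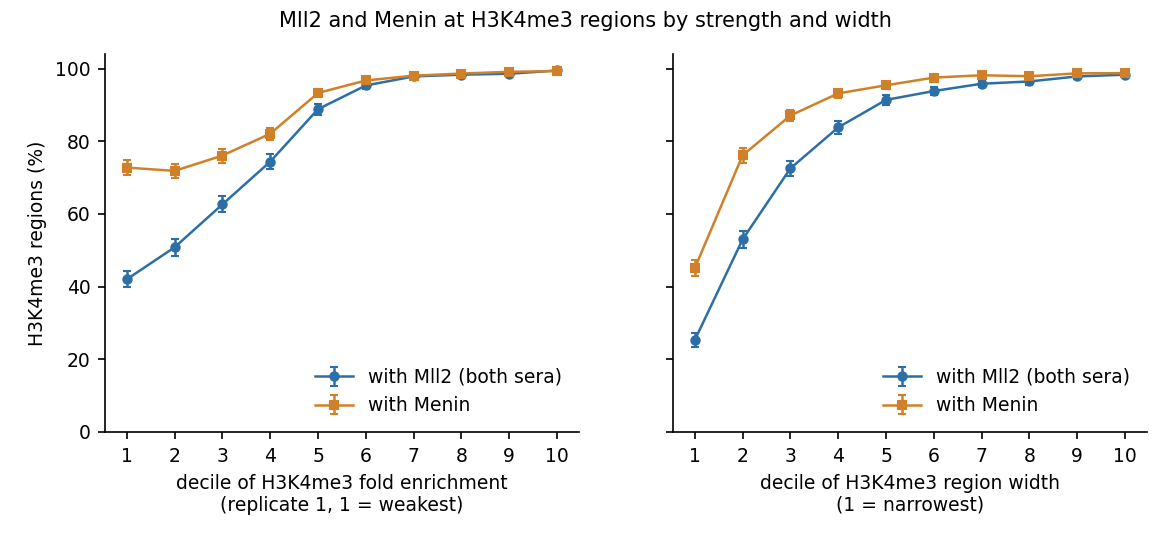
The share of H3K4me3 regions, in percent, that held an Mll2 region (circles) or a Menin peak (squares) is plotted by decile of H3K4me3 fold enrichment in replicate 1 (left) and of region width (right), with exact 95% binomial intervals. Mll2 coverage ran from 42.0% to 99.5% with fold enrichment and from 25.3% to 98.3% with width, and Menin lay above Mll2 in the weaker and narrower deciles. Mll2 had to be called with both sera, while Menin came from 1 longer list. Over all regions a peak of at least 1 serum covered 89.6% and Menin 88.8%. With peaks of at least 10-fold enrichment Mll2 covered 72.6% and Menin 63.9%.

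Mll2 and Menin occupied the same H3K4me3 regions far more often than each alone would give. Menin was present at 97.4% of the H3K4me3 regions with Mll2 and at 52.4% of those without it, an odds ratio of 34.5 (95% interval 30.6 to 38.8, Fisher's exact test, two-sided, with a p too small for the software to represent). The odds ratio was 12.6 (11.0 to 14.3) when regions were compared within quartiles of width and 15.1 (13.2 to 17.3) within deciles of H3K4me3 fold enrichment. It was 22.5 with peaks of a score of at least 100, 23.1 with equally long lists and 4.61 with peaks of at least 10-fold enrichment, a limit that left 18050 of the Menin peaks.

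H3K4me3 regions with Mll2 were wider than those without it. Their median width was 2101 bp, against 1060 bp for H3K4me3 regions without Mll2, a difference of 1041 bp (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The narrowest decile of H3K4me3 regions held Mll2 in 25.3% of cases and the widest decile in 98.3%. Of the 342 H3K4me3 regions wider than 5000 bp, 99.1% held Mll2 (97.5 to 99.8%) and 97.7% held Menin (95.4 to 99.0%). A wide region is more easily overlapped, and the difference was 415.5 bp when Mll2 was counted only with its summit within 500 bp of the region's midpoint, and 532 bp on average within deciles of H3K4me3 fold enrichment. In the midpoint setting the medians were 1975 and 1559.5 bp, and regions with Mll2 only away from the midpoint counted as without it.

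Within the 15362 Mll2 regions that carried both H3K4me3 and Menin, the position of the peaks was compared. Summits of the 2 Mll2 sera lay a median of 74 bp apart (quartiles 31 and 169 bp). The Mll2 summit of serum 9175 lay a median of 149 bp from the nearest Menin summit (57 and 317 bp), 200 bp from the nearest H3K4me3 summit of replicate 1 (90 and 358 bp) and 144 bp from that of replicate 3 (62 and 272 bp). In 74.9% of the 17524 pairs of a serum 9175 peak and an H3K4me3 region it overlapped, the Mll2 summit fell in the middle 40% of the region's width. These distances were not tested against a chance model.

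Menin had the longest list, and its peaks at both Mll2 and H3K4me3 had the highest median fold enrichment of its 4 classes, with overlapping quartile ranges. Of the 43544 Menin peaks, 43.3% overlapped peaks of both Mll2 and H3K4me3 in any library, 7.60% H3K4me3 without Mll2, 8.66% Mll2 without H3K4me3, and 40.4% (17607 peaks) neither. Menin peaks at both had a median fold of 11.3 (quartiles 8.90 and 14.9) and a median width of 1401 bp. The median fold was 8.94 with H3K4me3 alone, 8.70 with Mll2 alone and 8.56 (quartiles 7.45 and 9.93) with neither, and the median widths were 665, 752 and 535 bp. In the strongest decile of Menin peaks 93.1% overlapped H3K4me3 and 95.3% overlapped Mll2, against 39.8% and 45.8% in the weakest decile and a low point of 32.09% and 31.03% in decile 5. Few of the peaks at neither were called with a high score, with 16.8% of them reaching 100, against 87.2% of the Menin peaks at both.

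**Figure D3:**
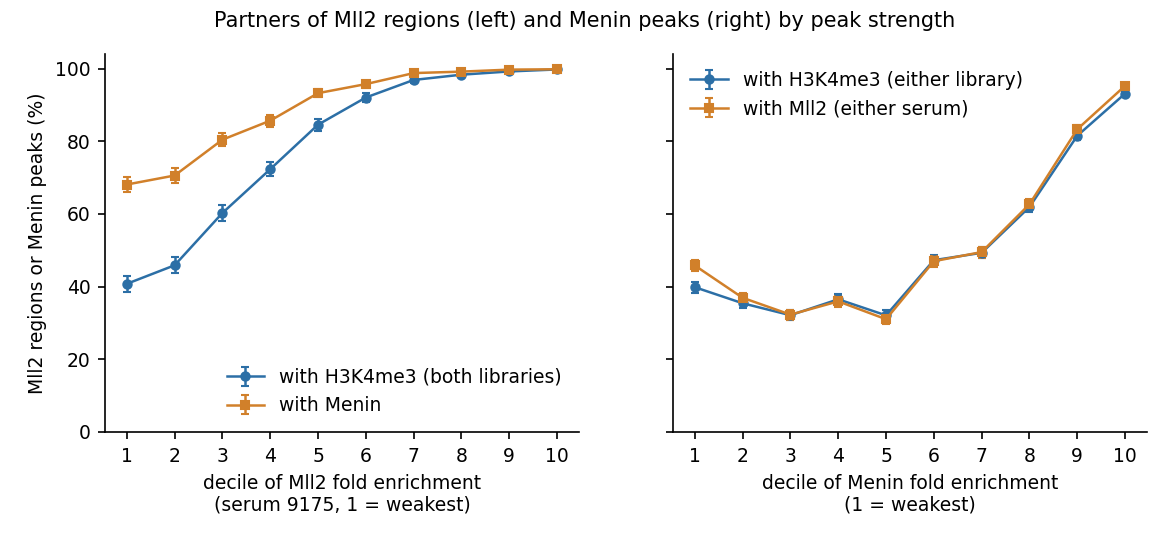
Left, the share of Mll2 regions, in percent, with an H3K4me3 region (circles) or a Menin peak (squares) by decile of Mll2 fold enrichment in serum 9175, and right, the share of Menin peaks with an H3K4me3 peak (circles) or an Mll2 peak (squares) of any library by decile of Menin fold enrichment, with exact 95% binomial intervals. H3K4me3 rose from 40.8% to 99.8% of Mll2 regions, while the partners of Menin peaks rose mainly in the upper deciles, to 93.1% and 95.3%.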

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

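The shifts of 50 kb to 1 Mb, the strata of H3K4me3 fold enrichment for the odds ratio and the width difference within those strata were chosen after the results were seen, and the other alternatives before the data were examined. All 101 alternative values over 11 results kept their direction and their side of the 0.05 threshold, which for the overlaps means only that they lay above chance placement. The setting of a false discovery rate of at most 1% removed 0 peaks and so says nothing about stability. The overlap of H3K4me3 replicate 1 peaks ran from 69.9% with summits within 500 bp to 91.4% with equally long lists of 19912 peaks, and that of serum 9172 peaks by serum 9175 from 74.7% with summits within 500 bp to 88.2% with a score of at least 100. Menin covered from 70.2% of Mll2 regions with a fold enrichment of at least 10 to 91.3% with a score of at least 100, and 63.9% of H3K4me3 regions with a fold of at least 10 against 88.8% in the report. H3K4me3 covered from 58.8% of the Mll2 peaks of either serum to 90.6% of those with a fold of at least 10. Mll2 covered 65.5% of H3K4me3 regions without replicate 3, when the weak peaks of replicate 1 entered, and 78.7% without replicate 1. The odds ratio of Mll2 and Menin was 4.61 with a fold of at least 10, 12.6 within width quartiles, 15.1 within deciles of H3K4me3 fold enrichment, 22.5 with a score of at least 100 and 23.1 with equally long lists, against 34.5 in the report, and the cause of these changes was not tested. The width difference of 1041 bp was 415.5 bp with the Mll2 summit near the midpoint and 532 bp within deciles of H3K4me3 fold enrichment. Shifts of 50 kb to 1 Mb, which keep peaks in peak-rich parts of a chromosome, gave mean chance overlaps of 4.27 to 10.6% and at most 12.1%. No paired analysis was possible because the groups that share the numbers 1 and 3 with the H3K4me3 libraries were not analysed here, and each Mll2 serum and Menin had 1 library. The alternatives intended for transcription start sites, gene groups and CpG density were not run for lack of annotation in mm9. The number of peaks did not follow depth across antibodies, the Menin library having the fewest kept tags (11550409) and the longest list (43544), and the effect of depth on weak sites was not tested.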

Other observations

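Except for the placement of Menin peaks relative to H3K4me3 regions, the tests below were chosen after the results they bear on were seen. Strong H3K4me3 was almost never without Mll2. Of the 9365 H3K4me3 regions with a replicate 1 fold of at least 40, 65 overlapped no Mll2 peak of either serum. Of those 65, 14 lay on chromosome X. Strong regions without any Mll2 peak made up 4.90% of the 286 strong regions on X and 0.562% of the strong autosomal regions. The Mll2 and Menin lists shared the site with the most tags, on chromosome 17 from 39979818 to 39985892 in serum 9175, with 9164 tags in serum 9172, 9478 in serum 9175 and 7174 in Menin. Its folds were 3.95, 7.29 and 2.47, and it had no H3K4me3 peak. The lists were not filtered for artefact sites here, and whether this site is one was not tested.

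Chromosome X stood apart in the share of its H3K4me3 regions with called Mll2 or Menin peaks. Of its 555 H3K4me3 regions 58.4% held an Mll2 region, against 78.2 to 85.7% on the 19 autosomes, 79.8% held a peak of at least 1 serum, against 87.1 to 93.0%, and 69.6% held Menin, against 85.1 to 94.2%. Weaker H3K4me3 on X does not account for it, since the odds of an Mll2 region on X were 0.276 times those on autosomes (0.223 to 0.343) within quintiles of H3K4me3 tags per kb, and 0.452 times (0.355 to 0.576) for a peak of at least 1 serum. A background that stays high on X in both Mll2 libraries, called against 1 input, is a candidate explanation for part of it but was not measured. Its stand-in was tags per kb of the peaks in a region divided by their highest fold. This quotient also varies with peak shape and with any fixed background behind the fold. It was taken at regions listed in all 5 lists (286 on X), so regions without called Mll2 or Menin peaks did not enter. On X it was 0.695, 0.633 and 0.659 times the autosomal value for H3K4me3 replicates 1 and 3 and Menin but 1.06 times for each Mll2 serum. Menin, with its low quotient on X, had a like loss over the H3K4me3 regions there (odds ratio 0.2697, 0.218 to 0.333, within the same quintiles). Fewer copies of X in the cells also stay open and cannot be told apart from lower occupancy, and the labels give no sex or karyotype. At the same regions listed in all 5 lists, tags per kb on X were 0.681 times the autosomal value in serum 9175, 0.701 in serum 9172 and 0.644 in Menin. The ratio was 0.747 in H3K4me3 replicate 3 and 0.834 in replicate 1, the last with an interval (0.787 to 0.894) that reached the lowest autosome at 0.882. A few peaks lay on chromosome Y, 5 and 3 in H3K4me3 replicates 1 and 3. Serum 9172 listed 2 there, serum 9175 listed 1 and Menin 0. Copy number itself was not measured.

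A second pattern was the 2990 Mll2 regions without an H3K4me3 peak in either library. Of them 51.5% held a Menin peak, called against another input, while shifts along the chromosome gave at most 5.55%. For the regions with Menin this argues against an artefact present only in the Mll2 input. A bias that recurs in the inputs of Mll2 and Menin alike was not tested and stays open. Shifts that keep peaks in peak-rich parts of a chromosome were not run for this overlap. For the other 48.5% no value decides. Whether tags piled up in ChIP and input alike could not be decided. Tags per kb divided by fold, a rough stand-in for the background, exceeded 3 times the serum 9175 list's median at 0.268% of these regions. Among Mll2 regions with H3K4me3 it did so at 0.0468%. Peaks were called only above their local background, so sites high in ChIP and input alike were less likely to be listed at all. Weak peaks near the calling threshold remain a candidate explanation for most of them. By serum 9175 fold enrichment, 42.3% of the weakest quintile of Mll2 regions lacked H3K4me3 against 0.299% of the strongest quintile. Shares by serum 9172 fold were not computed, and the strongest of these regions in that serum reached folds of 70.9, 51.5 and 47.0. No biological explanation was tested, since the groups analysed give none.

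A further pattern was the 17607 Menin peaks outside Mll2 and H3K4me3, 40.4% of the list. Nearness to the calling threshold may account for much of it, because among Menin peaks with a score of at least 100 the share outside both was 13.3%. Noise placed without regard to the marked regions is argued against, since 53.8% of these peaks lay within 10 kb of an H3K4me3 region, against a mean of 15.0% and at most 19.4% in 1000 shifts along the chromosome, and against a mean of 31.4% and at most 35.4% in shifts of 50 kb to 1 Mb. Open chromatin near promoters that gathers tags in any library was not tested and stays open beside Menin binding.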
